A study of Mus musculus with 20 samples.

How the data were processed

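RNA of pooled mouse ovarian follicles was measured on 20 single-channel Illumina BeadChip arrays, 1 array per pool. Per the labels, the follicles came from CD-1 mice 16 days old, and cultured follicles were held in 0.5% alginate in a medium with 10 mIU/ml recombinant FSH, with part of the medium exchanged every 2 days. Pools of 20 to 40 cultured follicles were released from the gel with 10 U/ml alginate lyase, and the labels describe the pools as independent experiments. Day 0 follicles were freshly isolated and not encapsulated.

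The deposited non-normalized file gives each probe's intensity on each array, which is a mean bead brightness on the linear scale with no normalization between arrays. The deposited detection p value of each probe is the share of negative control probes that were brighter on the same array. The authors also gave processed values on a log2 or similar scale, made with R 2.15.2. In these the 20 arrays share 1 distribution, but the transform is not stated. They were used only as an alternative.

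From the intensities, log2 values were computed with the neqc function of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p values, an offset of 16 and quantile normalization. Of 25697 probes, 14277 had a detection p under 0.05 on at least 3 arrays and were kept. Gene symbols were updated through the Entrez number with a RefSeq gene table of the mouse assembly GRCm38.p6, which gave a symbol for 23788 probes. The other 1909 probes kept the symbol of the file. The brightest probe of each symbol was used, which left 10684 genes of the 18113 symbols on the array. No coordinates are given, since the file does not state the genome build of its probe positions. Star and Inhbb were not among the tested genes.

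Samples were grouped by culture day, with 5 arrays at day 0 and 3 at each of days 2, 4, 5, 6 and 8. One limma model of the 6 groups was fitted over all 20 arrays, with 14 residual degrees of freedom. Each of 10 comparisons used limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over the genes, and a gene was called at an adjusted p under 0.05. Any change over the time course was tested with limma's moderated F. A fold is given as "at least" where the gene was detected on no array of the lower group, with the bound taken from the lowest detected signals of those arrays. Where it was detected on only some arrays of that group, the fitted difference is given, and its size rests in part on signals at background.

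The comparisons, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule takes the 10 largest rises and falls with non-overlapping arrays in the comparisons of day 2 with day 0, day 8 with day 0 and day 8 with day 2, and the 3 largest each way in the others. It adds Comp throughout, since the title of the paper known for this series names that gene. It also allows up to 4 members of each list per comparison with the smallest adjusted p, and any member of the oocyte, steroid hormone synthesis and granulosa cell lists. Symbols that are only clone or locus names were passed over. Not all items that the rule names are reported here.

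The 29 lists covered cell types, namely oocyte, granulosa cell, luteal cell, theca cell, fibroblast and stroma, smooth muscle and pericyte, endothelial cell, macrophage and leukocyte, erythroid cell, and ovarian surface epithelium. Lists for ovarian function covered steroid hormone synthesis, receptors and hormones of granulosa cells, and cumulus expansion with ovulation. The other lists were extracellular matrix, glycolysis, hypoxia response, cholesterol synthesis, cell cycle and division, immediate early response, targets of actin with serum response factor and YAP, heat shock with the unfolded protein response, and oxidative stress with metal response. Interferon response, TGF-beta with BMP signalling, Wnt signalling, hedgehog signalling, cell death with p53, mitochondrial respiration and cytosolic ribosome completed them. Each was compared with the other genes by limma's camera with a preset correlation of 0.01 in 6 comparisons, with adjustment over all 174 tests. Some genes stand in more than 1 list, such as Lhcgr, Inhba and Amh.

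The chip batch of the labels was checked with chip as a block and within each chip, since day 0 was present on all 5 chips. Within a chip, each day compared had only 1 or 2 arrays. Alternatives changed the background correction, the scaling, the detection filter, the choice of probe, the block, the weights and the spread estimate, and left out each array in turn. The deviations of day 2 and day 8 arrays with the same repeat number were correlated (0.207 to 0.511 over 3 pairs, 1 of them within a chip), as were those of day 6 and day 8 (0.106 to 0.402, 1 within a chip). In no other of 15 pairs of days were all 3 correlations over 0.1, and the labels do not say that the number marks a shared source. Replicates 2 and 3 also correlated across numbers, at 0.202 and 0.224 for days 2 and 8 and 0.164 and 0.129 for days 6 and 8. The correlations thus set replicate 1 apart from replicates 2 and 3 and do not show a pairing by number. Added after the data were seen were a run without 2 arrays that stood apart, a run with the trend against probe position removed, and the repeat number as a block in days 2 and 8 or in days 6 and 8 alone. For arrays, the number of pools limits the precision.

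The calls were tested on simulated data with 200 changed genes. These were drawn from the brighter genes, so recovery among the dimmest genes was not tested. Far more genes were called in the data, such as 3350 at day 2, so the shares of recovered and false calls need not hold there. In the simulated comparison of day 2 with day 0, over 11395 genes, 25.8% of genes changed by 1.5-fold, 77.3% of those changed by 2-fold and 98.5% of those changed by 4-fold were called, and 7.64% of calls were false. For day 8 with day 0, over 11376 genes, the shares were 20.9%, 78.8% and 100%, and 8.97% of calls were false. For day 8 with day 2, over 11329 genes, they were 13.6%, 67.7% and 97.0%, and 6.40% of calls were false. The list test called the changed list in each of these simulated comparisons and 0 of 40 unchanged lists by camera, of which 0, 0 and 1 had an unadjusted p under 0.05. The simulated noise was independent between genes and the unchanged lists were drawn at random. The simulation therefore cannot show false list calls that arise from correlated genes.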

Results

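The data described a time course of mouse ovarian follicles grown in alginate, a seaweed gel that keeps a follicle's shape. Gene expression was measured in pools of whole follicles at day 0 (n = 5) and after 2, 4, 5, 6 and 8 days of culture (n = 3 each). Each array detected between 11634 and 13312 probes (mean 12286 ± 445 SD, n = 20), and its median signal lay between 97.6 and 168. The first principal component held 54.9% of the variance, and its group means went from −58.2 at day 0 to −7.78 at day 2, 15.2 at day 4, 25.9 at day 5, 31.2 at day 6 and 32.6 at day 8. On the second component, with 12.2%, day 2 replicate 1 stood at 57.9 and all other arrays between −16.7 and 15.2. The SD of the log2 difference between that array and the other day 2 arrays was 0.66 and 0.69, against 0.36 between those. Of 10684 genes, 5499 (51.5%) changed over the time course by limma's moderated F. Changes below are log2 differences ± SE, with levels as log2 means ± SD. Their size depends on the processing: the median called change of a named gene was 75.7% as large without background correction and 54.2% as large in the authors' processed values, whose transform is not stated.

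**Figure D1:**
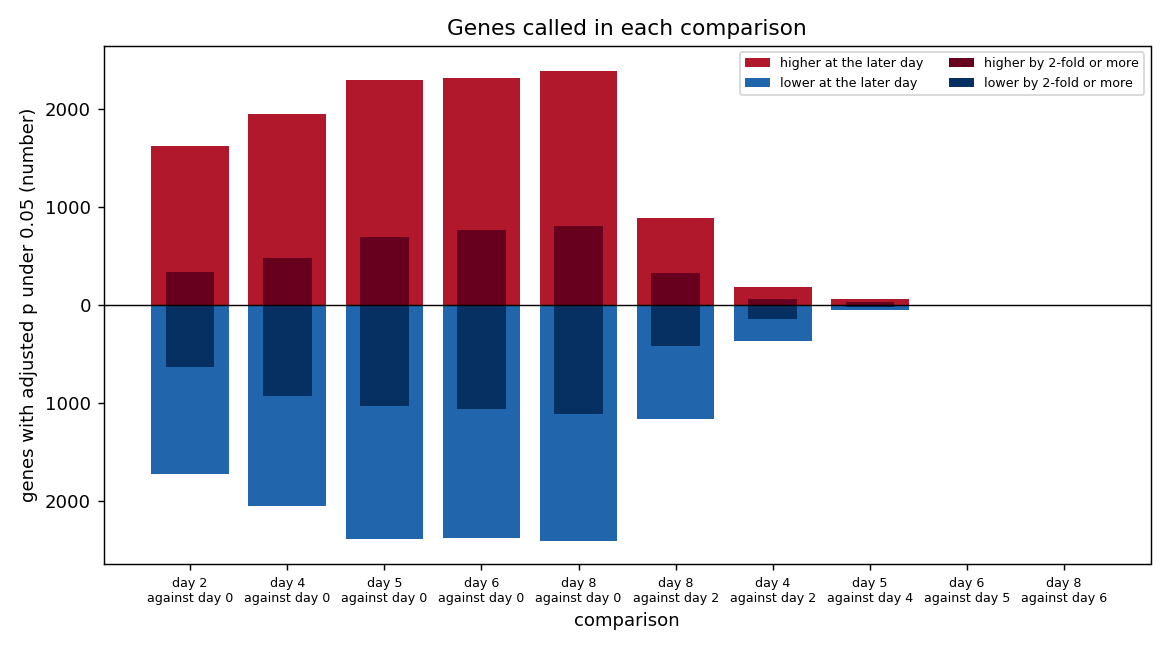
Bars give the number of genes called by limma in each comparison of culture days (higher above 0, lower below 0), with the darker inner bars for changes of at least 2-fold. The count against day 0 goes from 3350 at day 2 to 4794 at day 8, and the last steps have 4 and 0 calls.

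Comp encodes cartilage oligomeric matrix protein, an extracellular matrix protein of the thrombospondin family, measured by probe ILMN_2869110. It was not detected on any array of day 0 or day 2, and then reached 7.73 ± 1.1 at day 4, 10.1 ± 0.21 at day 5, 11.2 ± 0.26 at day 6 and 12.0 ± 0.36 at day 8 (SD, n = 3). Against day 0, Comp rose at least 4.95-fold by day 4, 26.1-fold by day 5, 56.6-fold by day 6 and 94.8-fold by day 8, where the fitted log2 difference was 7.04 ± 0.30 (adjusted p = 8.55e-13). The fitted differences of Comp from day 0 and day 2 are taken from a background level and are no bounds. Within chips, the log2 difference of Comp at day 8 was 6.62 and 7.20, and with chip as a block it was 7.11. At day 4 the chips gave 4.10, 2.13 and 2.06. The difference at day 2 was 0.17 ± 0.30 (adjusted p = 0.717). Without background correction the difference at day 8 was 5.01, and in the authors' processed values 3.80. Without day 4 replicate 1 the difference at day 4 was 2.13. The genes and lists plotted over time were picked from the named ones after their values were seen.

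**Figure D2:**
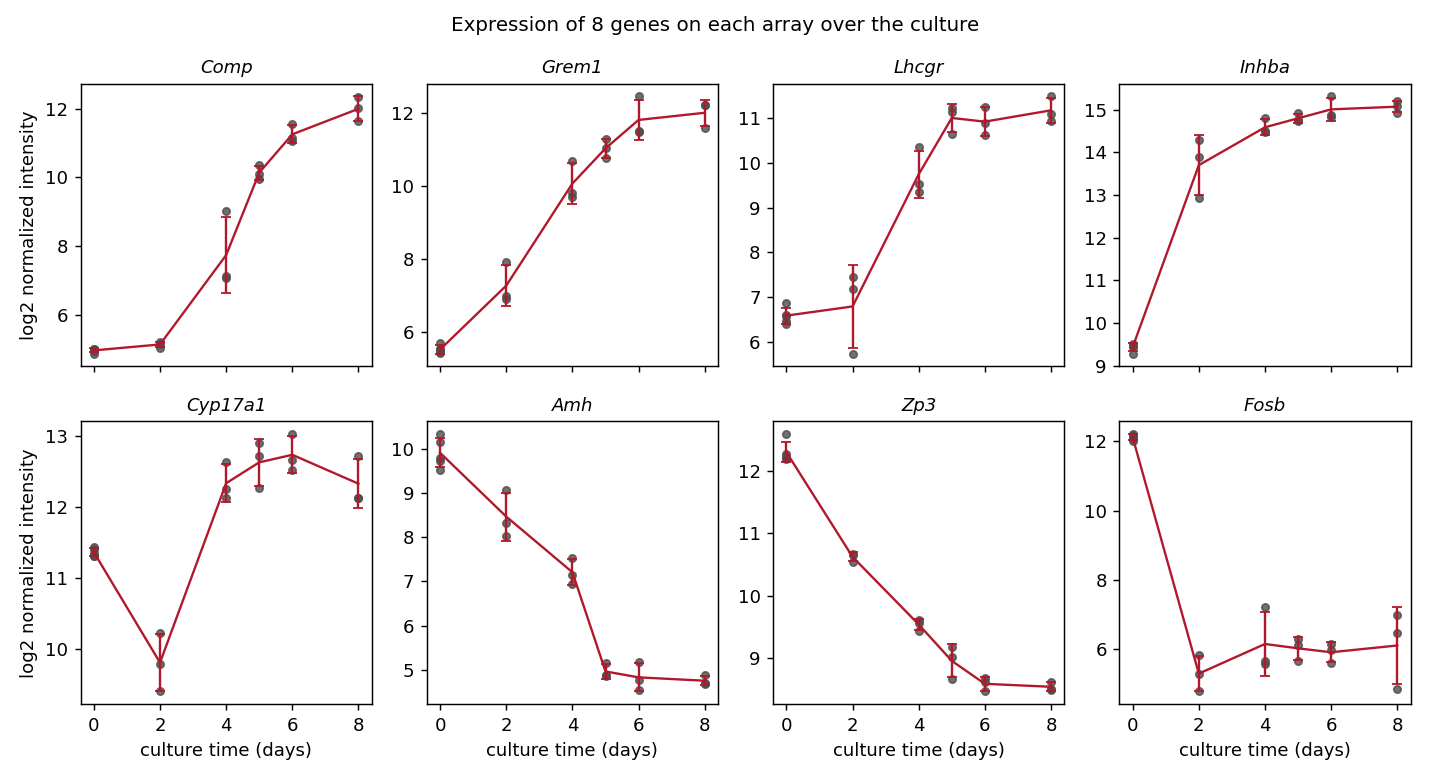
Points give the log2 normalized intensity of 8 genes on each array against culture time in days, and lines join the group means with bars of 1 SD (n = 5 at day 0, n = 3 later). Comp stays near its day 0 level at day 2. The mean of Lhcgr does too, but its day 2 arrays range from 5.74 to 7.45, against 6.40 to 6.87 at day 0. Both genes are higher from day 4, Inhba is higher from day 2, and Fosb is lower on every cultured array.

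The comparison of day 2 with day 0 asks what changes as isolated follicles enter the gel and the medium. Inhba, which encodes the activin and inhibin beta A subunit, rose by 4.26 ± 0.21, or 19.2-fold. Fshr, the FSH receptor, rose by 1.65 ± 0.21. Saa3, an acute phase serum amyloid gene, rose by 4.63 ± 0.52 (5.35 without day 2 replicate 1), and Spp1, which encodes osteopontin, by 3.81 ± 0.40. Hsd11b1, whose enzyme forms active glucocorticoid, rose at least 12.6-fold. Among the falls were the haemoglobin gene Hba-a1 (−5.51 ± 0.17) and Fosb, a subunit of the AP-1 transcription factor, whose fitted difference of −6.83 ± 0.39 rests on background, since 2 of 3 day 2 arrays did not detect it.

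Other large rises at day 2 were in Ugt1a10 (at least 9.41-fold), Adam23 (3.45), Adh1 (3.44), Scd1 (3.39), Gsta3 (2.80, but 0.88 by its other probe) and Lss (2.67). Areg, an EGF-like ligand of ovulation, fell at least 17.3-fold, Atf3 15.5-fold, Rsad2 17.1-fold and Cxcl10 13.1-fold. Klf4 (−4.34), Ccl4 (−4.28), Tnfrsf12a (−3.93) and Fos (−3.70) completed the largest falls. Ccl4 was detected on 1 of 3 day 2 arrays, and other probes gave −3.42 and −2.36 for Klf4 and −2.44 for Ccl4. The probe of Hba-a1 may not separate the paralogous alpha globin genes.

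Of 17 immediate early response genes, which are switched on within minutes of a stimulus, 15 fell and 0 rose (15 and 0 when adjusted over the list alone). Their median was −2.49 (camera adjusted p = 2.71e-18), −2.51 with chip as a block and −2.98 to −2.49 within chips. Fosb, Atf3, Klf4, Fos and Ier3 (−3.64 ± 0.19) were among them. Of 15 interferon response genes, 10 fell and 0 rose, and 11 fell and 1 rose when adjusted over the list alone. Ifit3 (−3.47 ± 0.15, but −0.98 by its other probe) and Isg15 (−3.30 ± 0.23), antiviral effectors, were among them. The interferon median was −1.78 (camera adjusted p = 6.8e-10), −1.67 with the block and −1.84 to −1.48 within chips.

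Of 28 oocyte genes, 24 fell at day 2 and 0 rose (25 and 0 when adjusted over the list alone). The median was −1.14 (camera adjusted p = 7.59e-15), −1.16 with the chip block and −1.24 to −0.99 within chips. Zp3 (−1.67 ± 0.13) and Zp1 (−1.45 ± 0.16), which encode proteins of the zona pellucida, were lower, as was Nlrp5 (−1.45 ± 0.13, and −1.46 and −0.89 by its other probes), a maternal effect gene. Of 18 genes of cholesterol synthesis, 17 rose and 0 fell by either adjustment, with a median of 1.48 (camera adjusted p = 3.05e-14), 1.52 with the block and 1.37 to 1.69 within chips. Nsdhl (2.07 ± 0.15, and 1.35 to 1.7 by its other probes), Mvd (2.16 ± 0.21) and Fdps (1.79 ± 0.13), enzymes of that pathway, were among them.

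Granulosa cells surround the oocyte, and 9 of their 18 tested markers rose while 1 fell (10 and 3 when adjusted over the list alone). The median was 0.56 (camera adjusted p = 0.0025, adjusted p = 0.268 with an estimated correlation), 0.52 with the block and 0.15 to 1.31 within chips. Without day 2 replicate 1 the median was 0.35 and the adjusted p = 0.0556. Of 18 receptors and hormones of granulosa cells, 8 rose and 1 fell (10 and 1 when adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.00782, adjusted p = 0.311 with an estimated correlation). Their block median was 0.45 and the chips gave 0.08 to 1.1, and without day 2 replicate 1 the median was 0.29 and the adjusted p = 0.127. Fshr and Prlr (1.69 ± 0.30), the prolactin receptor, rose, while Amh (−1.45 ± 0.22), the anti-Müllerian hormone of small growing follicles, fell.

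Of 14 steroid hormone synthesis genes, 8 rose and 3 fell at day 2 (9 and 4 when adjusted over the list alone), and the list was not called (median 0.72, camera adjusted p = 0.122). Stard4 (1.71 ± 0.15), a cholesterol carrier, and Hsd17b1 (2.25-fold), an oestradiol-forming enzyme of granulosa cells, rose. Cyp17a1 (−1.55 ± 0.19), the enzyme of androgen synthesis in theca cells, and Akr1b7 (at least 3.00-fold lower) fell. Of 15 genes of cumulus expansion and ovulation, 9 fell and 0 rose by either adjustment, with a median of −1.06 (camera adjusted p = 9.95e-07), −1.05 with the block and −1.34 to −1.17 within chips. Areg and Edn2 (at least 9.27-fold lower), which encodes endothelin 2, were among them.

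Markers of some other cell types were also lower at day 2. Of 16 endothelial genes 10 fell and 0 rose (11 and 0 when adjusted over the list alone), with a median of −0.80 (camera adjusted p = 1.56e-05), −0.76 with the block and −0.92 to −0.70 within chips. Cldn5 (−1.99 ± 0.26) and Tek (−1.50 ± 0.19), an angiopoietin receptor, were among them. Of 6 erythroid genes 5 fell by either adjustment, with a median of −1.77 (camera adjusted p = 1.32e-06), −1.75 with the block and −2.21 to −1.23 within chips. Of 17 macrophage and leukocyte genes 6 fell by either adjustment, Cd74 at least 3.15-fold and Cd14 by 3.04-fold. Their median was −0.54 (camera adjusted p = 9.76e-05, adjusted p = 0.0885 with an estimated correlation), −0.59 with the block and −0.79 to −0.55 within chips. Of 8 surface epithelium genes 4 fell by either adjustment, among them Krt18 (−2.14 ± 0.15), with a median of −0.59 (camera adjusted p = 0.0129, adjusted p = 0.122 with an estimated correlation), −0.65 with the block and −0.82 to −0.44 within chips.

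Of 29 cell cycle genes, 12 rose and 2 fell (13 and 2 when adjusted over the list alone), such as Top2a (1.27 ± 0.24) and Kif11 (0.91 ± 0.12). The median was 0.45 (camera adjusted p = 0.000182, adjusted p = 0.195 with an estimated correlation), 0.42 with the block and 0.42 to 0.50 within chips. Of 16 hypoxia response genes, 6 fell and 1 rose by either adjustment, with a median of −0.46 (camera adjusted p = 0.0114, adjusted p = 0.36 with an estimated correlation), −0.41 with the block and −0.59 to −0.21 within chips. Ndrg1 (−2.16 ± 0.23) and Vegfa (−1.29 ± 0.22), an angiogenic factor, were among those that fell. Of 19 heat shock and unfolded protein response genes, 8 fell and 1 rose (9 and 1 when adjusted over the list alone), with a median of −0.49 (camera adjusted p = 0.0239, adjusted p = 0.268 with an estimated correlation) and −0.51 with the block. The chips gave −0.38 to −0.21. Without day 2 replicate 3 the median was −0.31 (camera adjusted p = 0.0928), and with the most variable probe it was −0.49 (camera adjusted p = 0.0541).

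Of 19 targets of actin, serum response factor and YAP, 6 fell and 1 rose by either adjustment, with a median of −0.20 (camera adjusted p = 0.0412, adjusted p = 0.311 with an estimated correlation). Ccn1 (−3.23 ± 0.32, and −2.94 and −1.45 by its other probes) and Ccn2 (−2.91 ± 0.19), matricellular proteins, fell, while with chip as a block the list had a median of −0.16 and an adjusted p = 0.0822, and −0.55 to −0.16 within chips. The list's median was −0.11 without day 2 replicate 2 (camera adjusted p = 0.0988) and −0.13 with the most variable probe (camera adjusted p = 0.0944). Without day 2 replicate 1 it was −0.31 (camera adjusted p = 0.0126). Of 22 cytosolic ribosome genes 7 fell by either adjustment, with a median of −0.32 (camera adjusted p = 0.00686, adjusted p = 0.461 with an estimated correlation), −0.33 with the block and −0.61 to −0.09 within chips. Without day 2 replicate 1 the ribosome median was −0.11 and the adjusted p = 0.249, and with array weights they were −0.15 and 0.101.

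The remaining lists were not called at day 2. Of their members, rises and falls numbered 2 and 1 of 11 luteal, 3 and 3 of 14 theca, 4 and 3 of 18 fibroblast, 2 and 4 of 9 smooth muscle and 7 and 5 of 29 extracellular matrix genes. They numbered 1 and 3 of 17 glycolysis, 7 and 3 of 21 oxidative stress, 4 and 7 of 27 TGF-beta and BMP, 2 and 5 of 15 Wnt and 2 and 0 of 6 hedgehog genes. Cell death with p53 had 6 and 4 of 23, and mitochondrial respiration 1 and 0 of 29. When adjusted over the list alone, theca had 4 and 3, extracellular matrix 9 and 6, TGF-beta and BMP 5 and 7, Wnt 4 and 5 and mitochondrial respiration 0 and 0 by limma, and the others were as given. Median and mean differed in sign in the luteal (−0.03 and 0.31), fibroblast (0.13 and −0.09) and cell death lists (0.18 and −0.03). Single members with large changes included Wnt4 (−3.33 ± 0.22), Sfrp2 (2.57 ± 0.29), Ccng1 (2.00 ± 0.15), a p53 target, and Grem1 (1.76 ± 0.27). Grem1, a BMP antagonist, had an adjusted p = 0.235 in the authors' processed values.

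With undetected members at their bound the medians were 1.42 for cholesterol synthesis, −1.0 for cumulus expansion, −0.73 for endothelial, −1.33 for erythroid, −0.36 for leukocyte, −1.71 for interferon, −0.39 for hypoxia and 0.42 for cell cycle genes. In all, 3350 genes were called at day 2 by limma (1626 higher and 1724 lower), of which 335 were at least 2-fold higher and 636 at least 2-fold lower. With chip as a block the count was 3221, and on each of chips 1, 4 and 5 between 97.8% and 99.6% of the called genes had the same direction. These genes were called from the same arrays, which favours agreement, so the shares are no independent check of chip effects. Day 2 differed from day 0 in culture, medium, encapsulation and enzymatic recovery together, and these cannot be separated by the design.

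The comparison of day 8 with day 0 gives the change over the whole culture. Besides Comp, large rises were in Grem1 (6.51 ± 0.27, or 90.9-fold), in Inhba (5.64 ± 0.21) and in Lhcgr, the LH receptor (4.59 ± 0.30). Cyp19a1, the aromatase that forms oestrogens, rose by 3.78 ± 0.33. Amh fell at least 21.1-fold and was not detected on any array from day 5 on, and Slc18a2, a vesicular amine transporter, fell by 5.51 ± 0.47. Scd1 (5.00), Adam23 (4.99), Adh1 (4.31), Vcam1 (4.30) and Cxcl13 (at least 16.7-fold) rose as well. Hba-a1 fell at least 65.6-fold, Ccl4 16.7-fold, Rsad2 16.2-fold and Cxcl10 12.4-fold, and Fosb (−6.02), Atf3 (−4.21), Tmem184a (−4.19) and Tnfrsf12a (−4.11) were lower too. Other probes of Tmem184a and Ccl4 gave −2.45 and −2.61. Without day 8 replicate 1, which did not detect it, Fosb was at −5.39. Slc18a2 was detected on 2 of 3 and Atf3 on 1 of 3 day 8 arrays, and Grem1 on 4 of 5 day 0 arrays.

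Of 28 oocyte genes 27 fell at day 8 and 0 rose by either adjustment, with a median of −2.94 (camera adjusted p = 1.37e-20), −2.95 with the chip block and −2.91 within each chip. Zp3 (−3.75 ± 0.13), Zp1 (−3.75 ± 0.16), Nlrp5 (−3.38 ± 0.13, and −3.26 and −1.99 by its other probes) and Bmp15 (−3.54 ± 0.15), a growth factor of the oocyte, were among them. Of 14 steroid hormone synthesis genes 12 rose and 2 fell by either adjustment, with a median of 1.28 (camera adjusted p = 5.96e-05), 1.34 with the block and 1.2 to 1.54 within chips. Besides Cyp19a1, Hsd3b1 (2.38 ± 0.37) and Cyp11a1 (2.18-fold), enzymes of progesterone formation, rose. Of 18 cholesterol synthesis genes 17 rose by either adjustment, with a median of 2.11 (camera adjusted p = 2.38e-13), 2.17 with the block and 2.09 to 2.12 within chips.

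**Figure D3:**
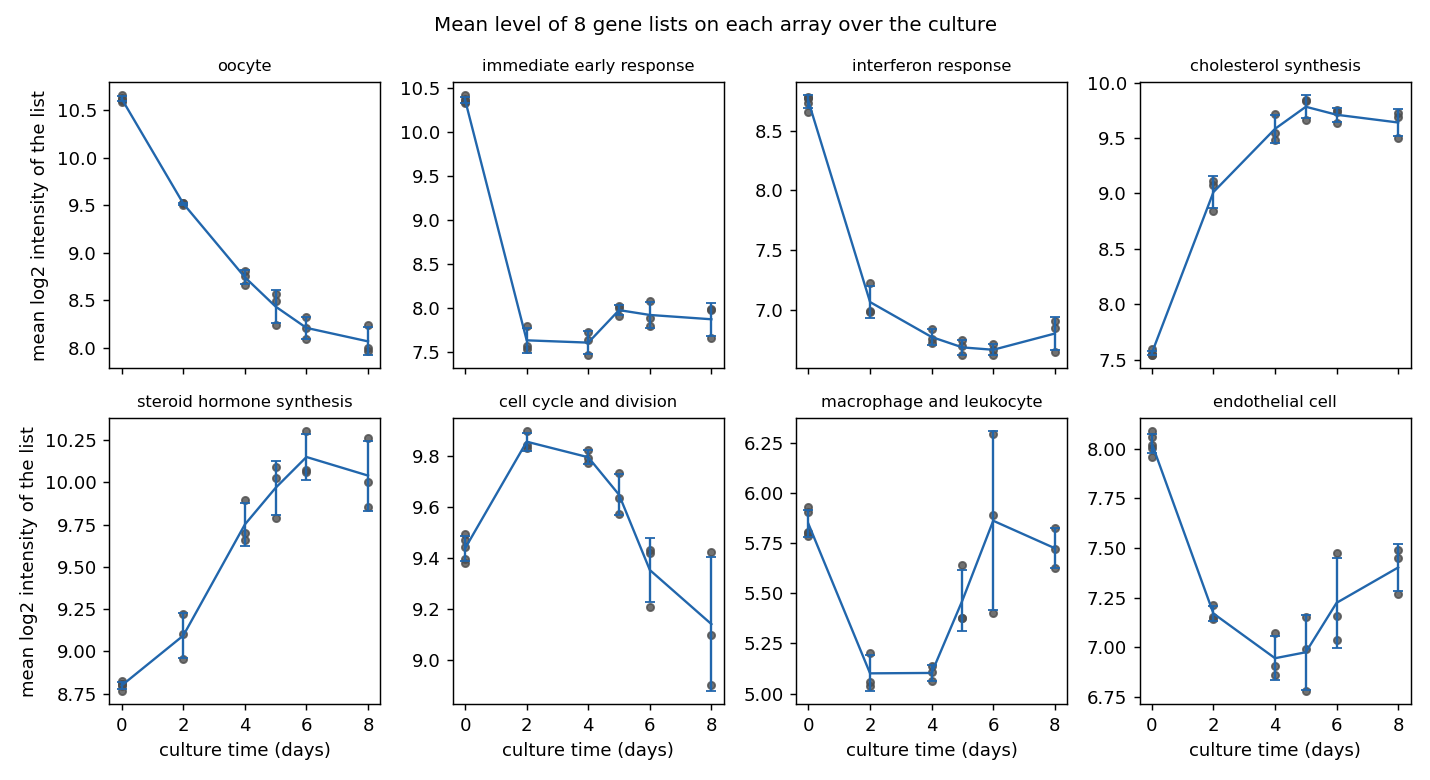
Points give the mean log2 intensity of the tested members of 8 gene lists on each array against culture time in days, and lines join the group means with bars of 1 SD (n = 5 at day 0, n = 3 later). The oocyte list declines throughout, the immediate early and interferon lists are lower on every cultured array than on any day 0 array, and the cholesterol synthesis list is higher on every cultured array.

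At day 8, 14 of 17 immediate early genes fell against day 0 and 0 rose (15 and 0 when adjusted over the list alone), with a median of −2.36 (camera adjusted p = 1.53e-11), −2.50 with the block and −2.78 to −2.52 within chips. Of 15 interferon genes 12 fell and 1 rose by either adjustment, among them Gbp2 (−3.51 ± 0.24), with a median of −1.75 (camera adjusted p = 5.7e-08), −1.72 with the block and −2.03 to −1.68 within chips. Of 15 genes of cumulus expansion and ovulation 9 fell and 2 rose (11 and 3 when adjusted over the list alone), with a median of −1.37 (camera adjusted p = 0.00208), −1.38 with the block and −1.46 to −1.23 within chips. Edn2 fell at least 8.76-fold, while Lhcgr, also on this list, rose.

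Of 17 glycolysis genes 10 rose and 1 fell by either adjustment, with a median of 0.86 (camera adjusted p = 0.000394, adjusted p = 0.285 with an estimated correlation), 0.82 with the block and 0.88 to 1.03 within chips. Aldoc (3.99 ± 0.27) and Eno1 (2.22 ± 0.28), glycolytic enzymes, were among them. Of 18 granulosa markers 9 rose and 2 fell (10 and 2 when adjusted over the list alone), with a median of 0.61 (camera adjusted p = 0.013, adjusted p = 0.34 with an estimated correlation) and 0.67 with the block. The chips gave 0.62 to 1.24, and without day 8 replicate 1 the median was 0.38. Of 18 receptors and hormones of granulosa cells 7 rose and 2 fell (7 and 3 when adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0342, adjusted p = 0.426 with an estimated correlation). That list had 0.27 with the block and 0.01 to 0.93 within chips, and without day 8 replicate 1 its median was −0.01 and its adjusted p = 0.08, while without day 8 replicate 3 the median was 0.56 and with array weights 0.13 (adjusted p = 0.0621). Prlr (3.86 ± 0.30) and Fshr (2.61 ± 0.21) rose.

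Of 11 luteal genes 6 rose and 1 fell by either adjustment, with a median of 0.68 (camera adjusted p = 0.0412, adjusted p = 0.23 with an estimated correlation), 0.75 with the block and 0.44 to 0.62 within chips. The luteal call was lost without background correction (adjusted p = 0.0558) and without day 8 replicate 1 (adjusted p = 0.0596) or day 0 replicate 4 (adjusted p = 0.0549), and in 5 further settings. Of 8 surface epithelium genes 6 fell by either adjustment, with a median of −1.34 (camera adjusted p = 0.00176, adjusted p = 0.0515 with an estimated correlation), −1.35 with the block and −1.62 to −1.18 within chips. Of 6 erythroid genes 5 fell by either adjustment, with a median of −1.70 (camera adjusted p = 0.000169, adjusted p = 0.062 with an estimated correlation), −1.77 with the block and −2.17 to −1.67 within chips.

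Of 16 endothelial genes 8 fell and 1 rose (9 and 1 when adjusted over the list alone), with a median of −0.42 (camera adjusted p = 0.0145, adjusted p = 0.224 with an estimated correlation), −0.44 with the block and −0.46 to −0.37 within chips. Of 18 fibroblast and stroma genes 10 fell and 2 rose (11 and 2 when adjusted over the list alone), among them Mfap4 (−3.60 ± 0.21), with a median of −0.58 (camera adjusted p = 0.00834, adjusted p = 0.262 with an estimated correlation), −0.57 with the block and −0.51 to −0.34 within chips. Of 9 smooth muscle genes 6 fell and 1 rose by either adjustment, Myh11 at least 3.86-fold, with a median of −0.80 (camera adjusted p = 0.0306, adjusted p = 0.283 with an estimated correlation), −0.90 with the block and −1.02 to −0.53 within chips. The smooth muscle call was lost with replicate as a block (adjusted p = 0.0683), with array weights (adjusted p = 0.0768), without day 8 replicate 1 (adjusted p = 0.0634) and without day 2 replicate 1 and day 8 replicate 1 (adjusted p = 0.0792).

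Of 19 targets of actin, serum response factor and YAP 10 fell and 1 rose by either adjustment, with a median of −0.50 (camera adjusted p = 0.00475, adjusted p = 0.185 with an estimated correlation), −0.57 with the block and −0.75 to −0.60 within chips. Of 19 heat shock and unfolded protein response genes 10 fell (11 when adjusted over the list alone), such as Chac1 (−2.75 ± 0.26), with a median of −0.56 (camera adjusted p = 0.00809, adjusted p = 0.201 with an estimated correlation), −0.60 with the block and −0.62 to −0.57 within chips. Without day 8 replicate 2 that median was −0.37.

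The other lists were not called at day 8. Rises and falls numbered 2 and 6 of 17 leukocyte, 0 and 10 of 29 cell cycle, 6 and 1 of 16 hypoxia, 12 and 6 of 27 TGF-beta and BMP, and 6 and 3 of 14 theca genes. They numbered 6 and 7 of 29 extracellular matrix, 8 and 2 of 21 oxidative stress, 2 and 0 of 6 hedgehog, 6 and 7 of 23 cell death, 2 and 1 of 29 mitochondrial and 0 and 4 of 22 ribosome genes. When adjusted over the list alone, theca had 6 and 5, cell death 7 and 7, mitochondrial respiration 0 and 0 and the ribosome 0 and 2 by limma, and the others were as given. Median and mean differed in sign in the cell death list (0.14 and −0.15), and the extracellular matrix list had a median of 0.04 with a downward camera test. The Wnt list had 1 rise and 7 falls of 15 (camera adjusted p = 0.0789), and with chip as a block its median was −0.37 and its adjusted p = 0.039. Wnt4, which acts in early ovarian development, was among the falls (−4.07 ± 0.22).

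With undetected members at their bound the medians were 1.98 for cholesterol synthesis, −1.15 for cumulus expansion, −1.25 for erythroid, −1.63 for interferon and −0.52 for fibroblast genes. In all, 4794 genes were called at day 8 by limma (2388 higher and 2406 lower), of which 810 were at least 2-fold higher and 1109 at least 2-fold lower. With chip as a block the count was 4522, and 98.9% of the called genes on chip 1 and 100% on chip 3 had the same direction. As at day 2, the genes were called from the same arrays, which favours agreement. The same factors as at day 2 differed between the groups.

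Days 4, 5 and 6 were compared with day 0 in the same way. At day 4 Inhba (5.15 ± 0.21), Scd1 (24.3-fold) and Grem1 (4.56 ± 0.27) rose, and Hba-a1 (at least 62.0-fold), Fosb (−5.98 ± 0.39) and Ccl4 (at least 15.8-fold) fell. At day 5 Grem1 (5.53), Inhba (5.36) and Adam23 (5.29) led the rises, and at day 6 Grem1 (6.31), Comp (at least 56.6-fold) and Inhba (5.57). Hba-a1, Fosb and Slc18a2 led the falls on both days by their fitted differences. The oocyte median went from −2.06 at day 4 to −2.50 at day 5 and −2.68 at day 6, with 27 of 28 genes called lower each time. With chip as a block these oocyte medians were −2.05, −2.38 and −2.65, and within chips they lay between −2.79 and −1.91. Steroid hormone synthesis had medians of 0.88 (10 rose and 2 fell), 1.01 (11 and 1) and 1.38 (12 and 1), and at day 4 its camera adjusted p was 0.000464 (adjusted p = 0.0708 with an estimated correlation). The block medians of steroid hormone synthesis were 0.95, 1.04 and 1.35, and the chips gave 0.81 to 1.44. Called genes numbered 4002 at day 4 (1949 higher and 2053 lower), 4685 at day 5 (2301 and 2384) and 4694 at day 6 (2316 and 2378) by limma, and 3955, 4220 and 4437 with chip as a block.

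The comparison of day 8 with day 2 lies within the culture, where both groups were encapsulated and recovered alike. Comp rose at least 93.8-fold, Grem1 by 4.75 ± 0.30, Lhcgr by 4.38 ± 0.33 and Igf2, an insulin-like growth factor, by 4.05 ± 0.22. Cyp17a1 (2.52 ± 0.22), Cyp19a1 (2.19 ± 0.37) and Cyp11a1 (1.55 ± 0.21) rose together. Slc18a2 (−4.44 ± 0.53), Saa3 (−3.84 ± 0.58), Gdf15 (−3.19 ± 0.28), a stress-induced cytokine, and Amh (at least 7.72-fold) fell. Without day 2 replicate 3 the change of Cyp19a1 was 1.58, and without day 2 replicate 1 that of Slc18a2 was −3.84. That of Saa3 ranged from −4.63 without day 8 replicate 3 to −3.21 without day 8 replicate 1, and it was −4.55 without day 2 replicate 1. Insyn2b (at least 11.6-fold), Sstr1 (at least 7.32-fold), Klk1 (at least 7.52-fold), Vcam1 (3.63), Lyz2 (3.30) and Cxcl13 (3.30) also rose. Tmem184a (7.98-fold lower, but −1.53 on the log2 scale by its other probe), Foxq1 (−2.87), Hsd11b1 (−2.83), Ccl7 (−2.80), the oocyte gene Oog4 (−2.75) and Sfrp2 (−2.64) also fell. The Lyz2 probe may not separate Lyz2 from its paralog Lyz1, and with chip as a block the change of Lyz2 was 2.69. Slc18a2 was detected on 2 of 3 and Gdf15, Foxq1, Ccl7, Oog4 and Sfrp2 on 1 of 3 day 8 arrays, and Lyz2 on 2 of 3 day 2 arrays.

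Of 14 steroid hormone synthesis genes 10 rose and 0 fell (12 and 0 when adjusted over the list alone), with a median of 0.64 (camera adjusted p = 1.08e-07), 0.74 with the block and 0.79 within chip 1, the only chip with both days. That chip held 1 array of each day, day 2 replicate 1 and day 8 replicate 1, the 2 arrays that stood apart. Values within chip 1 thus rest on these 2 arrays alone. Of 18 cholesterol synthesis genes 9 rose by either adjustment, with a median of 0.51 (camera adjusted p = 4.34e-05), 0.47 with the block and 0.54 within chip 1. Of 28 oocyte genes 23 fell (24 when adjusted over the list alone), Bmp15 by 2.46 ± 0.17 on the log2 scale, with a median of −1.68 (camera adjusted p = 3.1e-23), −1.65 with the block and −1.49 within chip 1. Of 29 cell cycle genes 20 fell and 0 rose (21 and 0 when adjusted over the list alone), with a median of −0.73 (camera adjusted p = 3.04e-11), −0.73 with the block and −0.56 within chip 1. Bub1b (−1.21 ± 0.19), a mitotic checkpoint kinase, was among them. Tyms, thymidylate synthase, was at −0.97 ± 0.14, while its other probes gave −0.66 (adjusted p = 0.035), −0.17 (adjusted p = 0.676) and 0.18 (adjusted p = 0.683).

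Of 17 glycolysis genes 12 rose and 0 fell by either adjustment, such as Aldoa (2.19-fold) and Pfkl (1.32 ± 0.22, but 0.05 by its other probe, adjusted p = 0.892), with a median of 0.81 (camera adjusted p = 4.23e-07, adjusted p = 0.159 with an estimated correlation), 0.93 with the block and 1.02 within chip 1. Of 16 hypoxia response genes 9 rose and 1 fell (12 and 1 when adjusted over the list alone), with a median of 0.96 (camera adjusted p = 9.14e-07, adjusted p = 0.111 with an estimated correlation), 0.98 with the block and 1.1 within chip 1. P4ha2 (1.84 ± 0.26), a collagen prolyl hydroxylase, and Pdk1 (1.48 ± 0.19), a kinase that restrains pyruvate oxidation, were among them. Of 27 TGF-beta and BMP genes 8 rose and 3 fell (10 and 4 when adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0119), 0.32 with the block and 0.12 within chip 1. Besides Grem1, which blocks BMPs, Id3 (0.83 ± 0.20), a BMP target, and Tgfbr3 (2.17-fold) rose, while the other probe of Tgfbr3 gave 0.44 and was not called.

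Of 17 macrophage and leukocyte genes 4 rose and 0 fell (6 and 0 when adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.00734, adjusted p = 0.23 with an estimated correlation), 0.34 with the block and 0.41 within chip 1. Lyz2 and Laptm5 (2.01 ± 0.43) rose, and without day 8 replicate 2 the list's median was 0.16, while with undetected members at their bound it was 0.18. Of 11 luteal genes 4 rose and 1 fell by either adjustment, Lhcgr and Prlr (2.17 ± 0.33) among the rises, with a median of 0.28 (camera adjusted p = 0.0302, adjusted p = 0.201 with an estimated correlation), 0.41 with the block and 0.20 within chip 1. Without day 8 replicate 1 the luteal median was 0.17 (adjusted p = 0.0751). It was 0.54 without day 8 replicate 3, 0.42 without day 2 replicate 1 and 0.45 without day 2 replicate 3.

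Of 18 fibroblast and stroma genes 7 fell and 0 rose (7 and 1 when adjusted over the list alone), such as Thy1 (−2.13 ± 0.30) and Pdgfra (−1.48 ± 0.19), a receptor of stromal and theca cells. The median was −0.54 (camera adjusted p = 0.000428, adjusted p = 0.148 with an estimated correlation), −0.66 with the block and −0.99 within chip 1. It was −0.26 without day 2 replicate 1, −0.84 without day 2 replicate 2 and −0.19 without both day 2 replicate 1 and day 8 replicate 1. Of 9 smooth muscle genes 6 fell and 1 rose by either adjustment, with a median of −0.80 (camera adjusted p = 0.00326, adjusted p = 0.163 with an estimated correlation), −0.76 with the block and −0.96 within chip 1. With undetected members at their bound that median was −0.36. Of 8 surface epithelium genes 4 fell (5 when adjusted over the list alone), with a median of −0.64 (camera adjusted p = 0.0185, adjusted p = 0.148 with an estimated correlation), −0.66 with the block and −0.83 within chip 1. Without day 2 replicate 1 the surface epithelium median was −0.34, and the call was lost without day 8 replicate 1 (adjusted p = 0.0544) with a stricter detection filter (adjusted p = 0.0503) and without day 2 replicate 1 and day 8 replicate 1 (adjusted p = 0.0791). Of 15 Wnt genes 5 fell (6 when adjusted over the list alone), Dkk3 (−2.33 ± 0.27) and Sfrp2 among them, with a median of −0.30 (camera adjusted p = 0.0256, adjusted p = 0.0708 with an estimated correlation), −0.49 with the block and −0.73 within chip 1. The Wnt call was lost without day 2 replicate 1 (median −0.09, adjusted p = 0.0922), without day 2 replicate 1 and day 8 replicate 1 (−0.12, adjusted p = 0.114), with array weights (−0.14, adjusted p = 0.0698) and with no detection filter (0.01, adjusted p = 0.12).

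The other lists were not called between day 2 and day 8. Rises and falls numbered 2 and 0 of 17 immediate early, 0 and 4 of 15 interferon, 3 and 2 of 16 endothelial, 0 and 1 of 6 erythroid, 4 and 2 of 18 granulosa, and 6 and 4 of 14 theca genes. They numbered 5 and 2 of 18 receptors and hormones, 4 and 3 of 15 cumulus, 2 and 6 of 29 extracellular matrix, 2 and 7 of 19 actin target, 0 and 2 of 19 heat shock and 4 and 1 of 21 oxidative stress genes. They numbered 0 and 1 of 6 hedgehog, 1 and 3 of 23 cell death, 0 and 0 of 29 mitochondrial and 0 and 1 of 22 ribosome genes by limma. When adjusted over the list alone, interferon had 0 and 5, endothelial 6 and 2, granulosa 6 and 2, receptors and hormones 6 and 2, extracellular matrix 4 and 8 and the ribosome 0 and 0, and the others were as given. In the granulosa list the median (0.22) and the mean (−0.10) differed in sign, as did those of the cumulus list (−0.08 and 0.35). Besides Comp, the extracellular matrix list held Mmp2 (−2.32 ± 0.27), a gelatinase.

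In all, 2055 genes were called between day 2 and day 8 by limma (891 higher and 1164 lower), of which 325 were at least 2-fold higher and 415 at least 2-fold lower. With chip as a block the count was 1496, and with only the arrays of the compared groups it was 954. On chip 1, 99.4% of the called genes had the same direction, but they were called from arrays that include the 1 array of each day on that chip.

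The comparisons of successive days ask between which days genes changed. From day 2 to day 4 Lhcgr (2.95 ± 0.33), Grem1 (2.81 ± 0.30) and Comp (at least 4.90-fold) rose, and Ccl7, a chemokine (−2.18 ± 0.33), Hsd11b1 (−2.17 ± 0.32) and Tmem184a (−2.05 ± 0.44) fell. In the authors' processed values Comp had an adjusted p = 0.0874, and without day 4 replicate 1 its change was 1.96, while Tmem184a then had an adjusted p = 0.0577. With chip as a block Comp was at 2.38 (adjusted p = 0.00215), and within chip 4 at 2.03. This step had 552 calls by limma (185 higher and 367 lower), 316 with chip as a block, 296 without day 4 replicate 1, 328 without day 4 replicate 3 and 16 with only the arrays of these days.

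From day 4 to day 5 Comp (2.40 ± 0.34, adjusted p = 0.00232), Zfp641 (2.06 ± 0.32) and Sstr1 (3.49-fold), a somatostatin receptor, rose. Amh (at least 2.89-fold), Foxq1 (−1.65 ± 0.32) and Gdf10 (−1.38 ± 0.25) fell. Without day 4 replicate 1 the change of Comp was 3.05, and within chip 2, the only chip with both days, it was 1.20, against 2.12 with chip as a block. With the block Sstr1 (adjusted p = 0.0628), Foxq1 (0.114) and Gdf10 (0.12) lost their calls, as did Amh in the authors' processed values (0.162) and Zfp641 without day 4 replicate 3 (0.0505). The step had 115 calls by limma (65 higher and 50 lower), 15 with chip as a block and between 8 and 212 when 1 array was left out.

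From day 5 to day 6, 4 genes were called by limma. Cxcl13, a chemokine that attracts B cells, rose by 1.88 ± 0.28 (adjusted p = 0.0237, and 0.133 without day 5 replicate 1). Zfp551 (1.24 ± 0.20) and Angptl1 (1.05 ± 0.18) rose and Metrnl (−1.03 ± 0.18) fell, and these lost their calls with chip as a block (adjusted p = 0.247, 0.208 and 0.171). Comp was 2.17-fold higher, with an SE of 0.34 on the log2 scale (adjusted p = 0.234). From day 6 to day 8 limma called 0 genes, with 392 at an unadjusted p under 0.05. Comp had a difference of 0.74 ± 0.34 (adjusted p = 1).

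Early and late calls were compared to see how many genes changed by day 2 stayed changed. Of the genes called against day 0 at day 2 and day 8, 2567 had the same direction at both (1134 higher and 1433 lower) and 47 had opposite directions. Independent lists would share 752, and simulated unchanged groups with the same day 0 arrays shared 0 in all 20 simulations. Few genes are called where nothing changed, so that 0 cannot show what the shared day 0 arrays add among changed genes. With the day 0 arrays divided between the comparisons, the count was 1703 to 1803 over 10 divisions. Each comparison then had fewer day 0 arrays, so a loss of power also lowers that count. The log2 changes had a covariance of 0.43 across genes, against 0.02 in the simulation, and genes are not independent replicates. Their correlation was 0.77, against 0.38 in the simulation of unchanged groups with the same day 0 arrays. With the day 0 arrays divided, the covariance was 0.410 to 0.427, against 0.431 undivided, so sharing these arrays added little to it.

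Across the 6 list comparisons, camera called 95 of 174 tests, and 40 of these held with an estimated correlation. These were oocyte and cholesterol synthesis in all 6 comparisons, and immediate early and interferon response in the 5 against day 0. Steroid hormone synthesis held at days 5, 6 and 8 and between day 2 and day 8, and cumulus expansion at days 2, 4, 5 and 8. Surface epithelium held at days 4, 5 and 6, erythroid at days 2, 4 and 6, and endothelial at days 2 and 4. Cell cycle and TGF-beta with BMP held between day 2 and day 8.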

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

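The tests of the 3 patterns weighed here were chosen only after the result was seen, and the counts of other splits were planned.

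Among 77 sets of day 0 values, 7 had 1 array far from the other 4 by Dixon's gap ratio, where chance gives about 1 in 20. Day 0 replicate 4 was that array on the second principal component (8.72 against −13.3 to −7.56, ratio 0.741) and for Cxcl10 (10.04 against 8.85 to 8.99, ratio 0.882) and Ccl4 (9.16 against 9.64 to 9.81, ratio 0.74). It was also apart in the mean level of the granulosa (10.68 against 10.53 to 10.56, ratio 0.836), glycolysis (9.70 against 9.36 to 9.46, ratio 0.711) and ribosome lists (14.00 against 14.07 to 14.08, ratio 0.808). In cholesterol synthesis, day 0 replicate 2 was at 7.60 against 7.55 to 7.56 (ratio 0.83).

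Of the genes called against day 0, 47 had opposite directions at day 2 and day 8, and the difference between day 8 and day 2 was called for all 47. Opposite calls against the same day 0 arrays make that difference large, so its call follows from the selection and adds no evidence. Of the 47 genes, 32 rose and then fell, and 15 fell and then rose. The androgen enzyme gene Cyp17a1 went from −1.55 at day 2 to 0.96 at day 8 (difference 2.52), and Igf2 from −0.59 to 3.46 (difference 4.05). The stress cytokine Gdf15 (difference −3.19), the amino acid enzyme Asns (−1.39), the mitotic kinase Aurka (−1.02) and the stromal genes Dpt (−1.83), Pdgfra (−1.48) and Tcf21 (−1.67) were higher and then lower than at day 0.

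Day 2 replicate 1 differed most from the other arrays of its day. An effect common to all arrays of chip 1 is argued against. The array's deviation correlated with probe position along the transcript at 0.334 (Spearman, across genes), while the other 5 arrays of chip 1 had a median of 0.03. An effect on part of chip 1 stays open, since the array's deviation correlated with those of day 6 replicate 1 (0.468) and day 8 replicate 1 (0.511) of that chip. With day 0 replicate 1, day 5 replicate 1 and day 6 replicate 2 of chip 1 it correlated at −0.140, −0.087 and −0.097. Day 6 replicate 1 and day 8 replicate 1 also share its repeat number, so chip and number cannot be told apart there. A bias by transcript length or RNA recovery on day 2 replicate 1 stays a candidate explanation, as the 0.334 exceeds the highest size outside day 2 (0.167, on day 8 replicate 1). A different mix of cells in that pool cannot be told apart from it, since the lists of cell types other than granulosa, luteal and oocyte deviated by at most 0.309, below the −0.67 of the ribosome list in size, but granulosa markers by 0.51 and granulosa receptors and hormones by 0.84. Probe position is a proxy for transcript length, and no biological explanation was tested.

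The oocyte list fell to a median of −2.94 at day 8. The fall was kept under 4 other ways of processing, whose highest median was −2.30, in the authors' processed values. Of these, only median scaling and cyclic loess clearly changed the scaling. All 4 bring the arrays to a common level, so they cannot show whether such scaling itself adds to the fall, and this stays open. A common dilution of oocyte RNA by the other cells of growing follicles may account for much of the fall, but cannot be told apart from changes of single genes. Among 15 bright oocyte genes the SD of the changes was 1.92 times their median SE, and differences in probe response were not measured. Changes in oocyte transcription over the culture days stay open and untested.

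Interferon and immediate early genes were highest at day 0. Leukocytes carried over into the freshly isolated pools may contribute. Of 17 leukocyte markers tested, the 6 detected on all day 0 arrays had a median of −1.36 at day 2. The medians of the whole list within chips were −0.79 to −0.55. The 6 markers were picked by their detection at day 0, which favours falls, so their median cannot decide the question. Laptm5, 1 of them, was higher again at day 8 (2.01 against day 2), the other 5 were not called between these days (−0.26 to 0.19, adjusted p = 0.417 to 0.789), and the interferon list had a median of −0.17 (camera adjusted p = 0.134). A response to handling at isolation, with the immediate early median at −2.49, cannot be told apart from other differences of day 0, since the design has no follicles held without isolation.

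For the comparisons with day 0, other splits of the arrays argue against chance for the count of calls, though not for single genes. With 56 splits the share cannot go below 1.79%, the value reached. The real split was the only 1 of 56 with a count as large at day 2 (3350, highest other 13), day 4 (4002 and 11), day 5 (4685 and 5), day 6 (4694 and 20) and day 8 (4794 and 10). It was also the only 1 of 100 for the time course (5499 and 562), the lists (95 and 76) and the overlap of day 2 with day 8 (2567 and 13). Since another draw gave 76 list calls, the count of 95 does not exclude chance for single list calls. For groups of 3 against 3 the 10 splits are too few for a share under 0.05. Of the splits that part all 3 numbered pairs, as the real one does, the highest other count was 2 from day 2 to day 8 and 11 from day 6 to day 8, and of those that part 1 pair it was 63 and 1. The real and the highest other counts were 2055 and 63 from day 2 to day 8, 552 and 5 from day 2 to day 4, 115 and 2 from day 4 to day 5, 4 and 10 from day 5 to day 6 (2 splits as large) and 0 and 11 from day 6 to day 8 (10 as large).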

How the results depend on the processing

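Chosen only after the data were seen were the run without day 2 replicate 1 and day 8 replicate 1, the run with the probe position trend removed and the replicate block in 2 days alone. Of 666 called changes of named genes, 641 kept their call with chip as a block and 638 with median scaling, and of 95 list calls 91 kept theirs with chip as a block. With the probe position trend removed, 660 of the named changes and 94 of the list calls were kept. The list call lost was that of receptors and hormones at day 6 (camera adjusted p = 0.0509). The ribosome call at day 2, which was lost without day 2 replicate 1, was kept. No called change of a named gene or list turned its direction, except 2 list medians whose calls were lost. That of the receptors and hormones list at day 8 was −0.01 without day 8 replicate 1 (adjusted p = 0.08) and without both arrays that stood apart (adjusted p = 0.119), and that of the Wnt list from day 2 to day 8 was 0.01 with no detection filter (adjusted p = 0.12). Counts that moved over 1.5 times were those below, and the cause was not tested. From day 4 to day 5, 115 calls became 68 with median scaling, 15 with chip as a block, 1743 with array weights and 239 without both arrays that stood apart. From day 5 to day 6, 4 became 2 with the authors' values, 1 with chip as a block, 1 with the replicate number as a block, 2 with array weights, 1 with only the compared arrays and 50 without both arrays. From day 2 to day 4, 552 became 316 with chip as a block and 16 with only the compared arrays, and from day 2 to day 8, 2055 became 954 with those. From day 6 to day 8, 0 calls by limma (392 at an unadjusted p under 0.05) became 7 without both arrays. List calls went from 95 to 40 with an estimated correlation.

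With 1 array left out, counts against day 0 ranged from 2935 to 3449 at day 2, 3315 to 4436 at day 4, 3973 to 5151 at day 5, 4214 to 5115 at day 6 and 4118 to 5254 at day 8. They ranged from 1394 to 2199 from day 2 to day 8, 296 (without day 4 replicate 1) to 589 from day 2 to day 4, and 8 (without day 4 replicate 3) to 212 (without day 2 replicate 1) from day 4 to day 5. From day 5 to day 6 they ranged from 0 (without day 5 replicate 1) to 37 (without day 6 replicate 2), and from day 6 to day 8 from 0 to 7 (without day 8 replicate 1). The time course ranged from 4930 to 5952, the lists from 90 to 96 and the overlap from 2290 to 2638. From day 5 to day 6, with 3 of 4 calls higher, the share of higher genes ranged from 50.0% to 100% over the alternatives that made a call. In the other comparisons it moved by over 10 points at day 2 with cyclic loess (38.0% against 48.5%), and with median scaling at day 5 (35.0%), from day 2 to day 8 (32.6%), from day 2 to day 4 (20.6%) and from day 4 to day 5 (22.1%). Over all days, arrays with the same number had a mean correlation of 0.0445 (−0.262 to 0.511) and 10 of 18 correlated best with their own number, so the replicate block over all days is given only as an alternative. For day 8 with day 2, arrays with the same number were correlated, but replicates 2 and 3 were so across numbers too (0.202 and 0.224). A replicate block in these days gave 2436 calls rather than 2055, kept all 13 list calls and all 100 calls of named genes and added 6. For day 8 with day 6 such a block gave 0 calls by limma, as without it. Signal over background limits the size of changes in dim genes, which is why folds against undetected groups are given as bounds.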

Other observations

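The values here were chosen after the results were seen. Of 10684 genes, 6352 were called neither from day 0 to day 2 nor from day 2 to day 8. The most frequent other patterns were a rise (1186 genes) or a fall (1091 genes) by day 2 with no later call. A rise after day 2 only was called for 537 genes, a fall in both steps for 498, the oocyte genes Zp3 and Bmp15 among them, and a fall after day 2 only for 445. A rise in both steps was called for 219 genes, among them Inhba and Grem1. A rise and then a fall was called for 221 genes, among them Saa3 and Hsd11b1, and a fall and then a rise for 135, among them Cyp17a1 and Ccn2.

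The mean level of the macrophage and leukocyte list was 5.79 to 5.93 on the day 0 arrays, 5.04 to 5.20 at day 2 and 5.06 to 5.14 at day 4. It was 5.38 to 5.64 at day 5 and 5.63 to 5.83 at day 8, while the 3 arrays of day 6 ranged from 5.4 to 6.29. These means lie near background, as the lowest detected log2 signal of an array was 5.29 to 5.70. Only 6 of the 17 members tested were detected on all day 0 arrays. The lysozyme gene Lyz2, whose probe may also bind Lyz1, had its widest spread at day 6 (9.01 ± 1.6 SD, n = 3), and without day 6 replicate 2 its change against day 0 was 2.18 rather than 3.11.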
